A study of Saccharomyces cerevisiae with 16 samples.

How the data were processed

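Expression was measured on 16 Affymetrix Yeast Genome 2.0 arrays, 2 for each of 8 strains of the budding yeast Saccharomyces cerevisiae. The chaperonin CCT (also called TRiC) is a ring complex of 8 different subunits that folds actin, tubulin and other proteins. The wild-type strain (WT) and 7 mutant strains (MA1, MA2, MA3, MA5, MA6, MA7 and MA8) were grown at 30 °C to an optical density of 0.5, per the labels' protocols. Each mutant carries an aspartate-to-glutamate substitution in 1 CCT subunit. Total RNA was copied into biotinylated RNA and hybridized, 1 array per sample.

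The deposited values are log2 expression values per probe set. Partek and RMA are named in the submitters' processing notes, with no version stated. RMA corrects the background, normalizes between arrays and summarizes the probes of a probe set, so the deposited log2 values are relative levels and a uniform change of all transcripts would not be seen in them. No scanner files were used here. The medians over all 10928 probe sets lay between 6.40 and 7.12 on the 16 arrays, and the medians over the tested probe sets between 10.46 and 10.50.

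The array carries probe sets for S. cerevisiae and for the fission yeast S. pombe. The platform annotation, updated through gene identifiers to the symbols of the R64 gene table (12 symbols differed), paired 5498 probe sets with exactly 1 S. cerevisiae gene, and these were tested. They stand for 5449 genes, 47 of which had more than 1 probe set; such a gene was represented by the probe set with the highest mean. A further 1746 probe sets were paired with S. pombe genes, 1 was paired with several genes, and 3683 were not listed in the annotation. The unlisted ones comprised 166 control, 47 reporter and 3470 unnamed probe sets. The build behind the array is not given in the sources used here, so no coordinates are printed and the gene table was used only for names, chromosomes and neighbour order.

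Groups were taken from the sample titles. A linear model with 1 mean per strain was fitted to the 16 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual and 2.02 prior degrees of freedom), with no further normalization. The contrasts were each mutant against WT, the mean of the 7 mutants against WT, the 21 pairs of mutants, each mutant against the mean of the others, and a moderated F test among the mutants. Tests were two-sided with Benjamini-Hochberg adjustment, and a probe set was called at an adjusted p under 0.05. The 47 gene lists were tested in each mutant with camera at a preset correlation of 0.01, adjusted over all 329 pairs of list and strain, and again with an estimated correlation and with fry. These tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named the CCT and marker genes in every strain, genes called in the contrasts, and up to 4 members with the largest absolute moderated t in each list that camera called; the text gives the leading member of the 4 lists with the smallest p in a strain. Other genes were chosen after their values were seen, which is said where they appear.

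Because the labels were contradicted by marker genes, values were also described array by array, as deviations from the median of the 16 arrays. A list's median on an array was set against 10000 random lists of the same size matched on mean level in 20 bins, as a description of that array. Similarity of arrays was the correlation, across the tested probe sets, of deviations from the probe set means. Within-pair squares of the labelled pairs were compared with 100000 random pairings of the arrays. These steps used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and were chosen after the data were seen. No array was moved to another group.

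On simulated data with the residual spread of the labelled strains, the fit of 5498 probe sets for MA1 against WT recovered 85 of 100 changes of 2-fold and 100 of 100 changes of 4-fold, with 12 false calls. Each change was put on both MA1 arrays, so this recovery assumes correct labels and does not hold if arrays are exchanged between strains. In a simulation of the arrays with strain effects larger than the noise in every probe set, all 16 lay nearest to the other array of their strain. Without strain effects 0 did. The simulated noise was smaller than the differences seen within labels, so this checks the method only and is no benchmark for the observed count. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples. That spread may be technical in part. It also holds differences within a label as large as that of URA3, at 8.07 and 11.95 on the arrays labelled WT. For arrays the number of samples limits the precision. Alternatives covered normalization, dim probe sets, all probe sets, 1 probe set per gene, variance trend, unmoderated tests, array weights, a 2-fold minimum, a replicate block, fits of 2 strains alone, and leaving out each array.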

Results

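The series measured transcript levels in a wild-type yeast strain and in 7 strains that each carry an equivalent aspartate-to-glutamate substitution in 1 subunit of the chaperonin CCT, and its title asks whether equivalent substitutions give different phenotypes. The labels place D96E in TCP1 (the first CCT subunit) in MA1, D90E in CCT2 in MA2, D91E in CCT3 in MA3, D117E in CCT5 in MA5, D89E in CCT6 in MA6, D96E in CCT7 in MA7 and D98E in CCT8 in MA8. Every strain had 2 arrays. All strains carry a tag at CCT6, marked with KanMX4 in WT and MA6 and with URA3 (orotidine-phosphate decarboxylase, of uracil synthesis) in the other 6 mutants.

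The marker gene went against the labels. URA3 was between 7.23 and 8.12 (log2) on 4 arrays and between 11.70 and 12.05 on the other 12, a gap of 11.95-fold. By genotype the 4 arrays labelled WT and MA6 should lack the marker. Of these, the array labelled WT replicate 1 had a low value of 8.07, while WT replicate 2 had 11.95 and the arrays labelled MA6 had 11.70 and 11.90. The other 3 low arrays were labelled MA5 replicate 1 (8.12), MA2 replicate 2 (7.23) and MA8 replicate 1 (7.30), strains whose label carries URA3. In all, 6 of the 16 arrays opposed their label, 3 in each direction. All 4 URA3 probe sets on the array, 3 of them control probe sets, had the same 4 lowest arrays. Strain names below therefore mean "the arrays labelled" with that name, and every direction between strains rests on labels that URA3 contradicts.

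The tagged gene itself followed URA3. CCT6 lay between 11.46 and 11.94 on those 4 arrays and between 12.46 and 12.94 on the other 12. URA1 (dihydroorotate dehydrogenase) was between 13.33 and 13.73 on the 4 and between 12.95 and 13.27 on the others, and URA4 (dihydroorotase) between 12.53 and 12.93 against 12.25 to 12.52. URA10 had no such order: it was 8.82 on the array labelled WT replicate 1 and 9.73 on MA8 replicate 1.

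Other CCT genes also parted arrays of the same label. CCT2 was 10.64 on the array labelled MA1 replicate 1 and 10.47 on MA6 replicate 1, but 12.97 and 12.93 on the second arrays of those strains, and 12.97 and 13.06 in MA2, whose label names CCT2. CCT3 was 10.16 on MA1 replicate 2 and 10.22 on MA6 replicate 2, and at least 12.07 on the other arrays; the arrays labelled MA3 had 13.03 and 12.37. CCT5 was lowest on MA7 replicate 1 (12.78) and MA2 replicate 1 (12.83), close to the next value of 12.91. TCP1 ranged over strain means from 12.54 ± 0.18 in MA6 to 12.80 ± 0.08 (SD, n = 2 each) in WT, and CCT4 from 12.98 ± 0.13 in MA6 to 13.09 ± 0.02 in MA5. No mutated gene differed from WT in its own strain. The log2 change was -0.25 ± 0.10 for TCP1 in MA1, -0.06 ± 0.76 for CCT2 in MA2, 0.27 ± 0.67 for CCT3 in MA3, -0.02 ± 0.27 for CCT5 in MA5, 0.31 ± 0.50 for CCT6 in MA6, 0.15 ± 0.23 for CCT7 in MA7 and 0.03 ± 0.23 for CCT8 in MA8 (± SE). The smallest of their limma adjusted p values was 0.61, and leaving out 1 array turned the sign of each except TCP1. A substitution need not alter the level of a transcript, so these log2 changes do not check the mutated subunits. The levels themselves did part arrays of 1 label. The 2 lowest CCT2 arrays lay 4.90-fold below the next and the 2 lowest CCT3 arrays 3.60-fold, in both cases on arrays labelled MA1 and MA6.

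Of the remaining genotype markers, LEU2 (leucine synthesis) was 13.95 and 13.96 on the arrays labelled WT replicate 1 and MA5 replicate 1 and between 13.54 and 13.66 on the other 14. PRB1 (vacuolar protease B) was 10.45 and 10.64 on those same arrays and at least 11.14 elsewhere. PEP4 and PRC1, further vacuolar proteases, had 11.06 and 10.54 on WT replicate 1 and 11.14 and 10.65 on MA5 replicate 1, their lowest values, against 11.49 and 11.03 on WT replicate 2. GAL2, the galactose permease, stayed between 5.82 and 6.59 on every array. TRP1 was not analysed here.

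**Figure D1:**
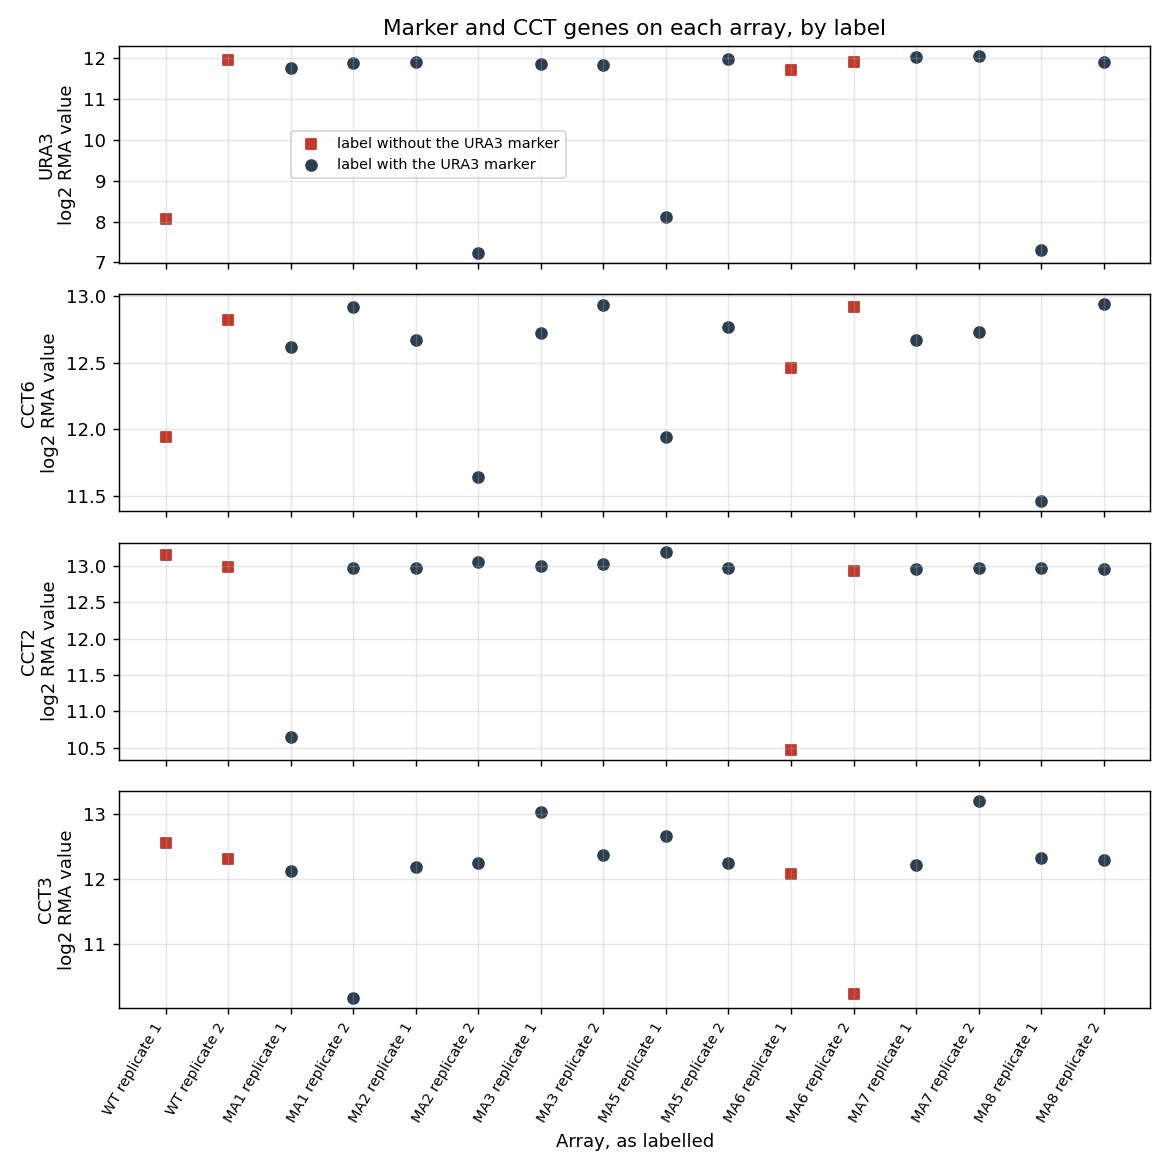
Log2 RMA value (vertical axes) of URA3, CCT6, CCT2 and CCT3 on each of the 16 arrays (horizontal axis, as labelled); squares are arrays whose label lacks the URA3 marker and circles those whose label carries it, 1 point per array. URA3 was at 8.12 or below on 4 arrays, of which 1 is a square, and 3 squares lie at 11.70 or above.

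Arrays of one label were on the whole no closer to each other than to arrays of other labels. The root mean square difference over 5498 probe sets had a median of 0.37 (log2) over the 8 same-label pairs and of 0.36 over the other 112 pairs. In 7 of the 8 strains the deviations of both arrays correlated below 0 across probe sets, down to -0.44 in MA5, and in MA8 they correlated at 0.60. Probe sets are not independent replicates, so no p is given for these values. By these correlations, 2 of the 16 arrays, both labelled MA8, had the other array of their own label as the nearest. The highest correlations joined WT replicate 1 with MA5 replicate 1 (0.94), MA1 replicate 1 with MA6 replicate 1 (0.93), MA3 replicate 1 with MA7 replicate 2 (0.85) and MA2 replicate 1 with MA7 replicate 1 (0.76). Within-pair squares as small as those of the labelled pairs came from random pairings with a one-sided permutation p of 0.57 (100000 pairings).

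**Figure D2:**
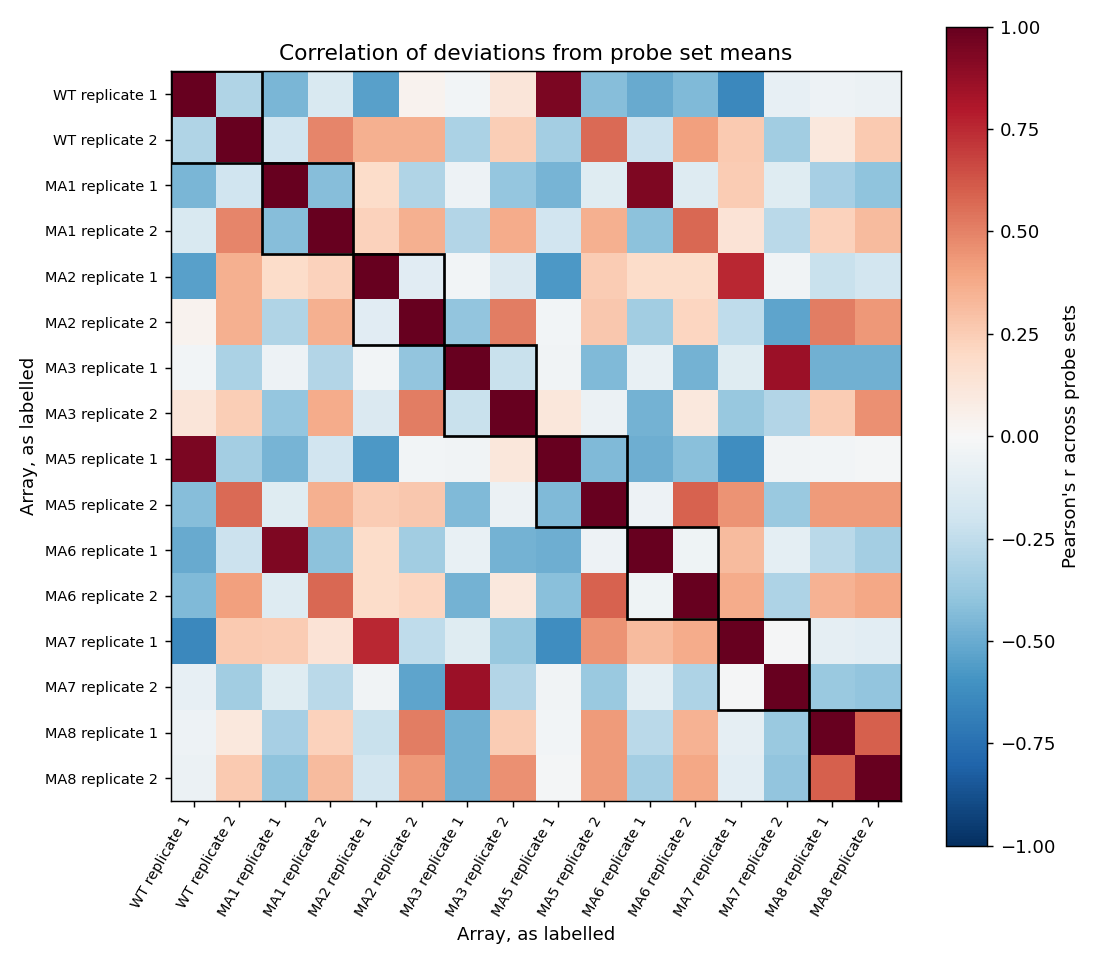
Pearson's r across 5498 probe sets between the deviations of the 16 arrays from the probe set means (both axes list the arrays as labelled; colour gives r; black squares frame the 2 arrays of a label). Of the framed pairs MA8 alone is above 0, at 0.60, while WT replicate 1 and MA5 replicate 1 reach 0.94.

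For each mutant against WT, which asks what each substitution does to expression, no probe set passed an adjusted p of 0.05 in limma. At an unadjusted p under 0.05 there were 227 probe sets in MA1, 41 in MA2, 258 in MA3, 18 in MA5, 635 in MA6, 493 in MA7 and 223 in MA8, where chance alone gives about 275 of 5498. That figure assumes correct labels, and counts vary widely around it because probe sets are not independent. A count above or below 275 is therefore no evidence for or against an effect in a strain. The smallest adjusted p was 0.40, in MA6. The unmoderated linear model also called 0. Without the 6 arrays that oppose their label, an alternative chosen after seeing the data, each of the 6 mutants left had 1 call, and all 6 calls were URA3 itself. Those arrays were chosen by URA3, so that call follows by construction and is no evidence of a difference between strains.

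Differences among the mutants, the question of the title, were not called either. The moderated F test called 0 probe sets, with 147 at an unadjusted p under 0.05 and a smallest adjusted p of 0.89. The mean of the 7 mutants against WT gave 0 calls and 258 at an unadjusted p under 0.05. The 21 pairs of mutants gave 0 calls in all, with 27 to 536 probe sets at an unadjusted p under 0.05, and the 7 comparisons of a mutant with the others gave 0 calls, with 47 to 362. The unmoderated model called 0 in each. Fold changes of different mutants against WT correlated across probe sets with a median r of 0.60 over the 21 pairs (0.10 to 0.96). Simulated unchanged strains against shared simulated WT arrays gave 0.50, and the covariances were 0.038 and 0.031. The simulation gave every strain the same spread. The 2 arrays labelled WT differed by a root mean square of 0.42, where the same-label median was 0.37. The simulation therefore cannot tell a change shared by the mutants from the spread of the WT arrays. The 2 WT arrays could not be split into sets of at least 2, and part or all of the excess may come from them.

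Among the 47 gene lists, camera with its preset correlation called 83 of 329 pairs of list and strain, 64 higher and 19 lower than WT, in 27 lists. All 7 strains were compared with the same WT arrays, so a call shared by several strains is not a repeated finding. None was called with an estimated correlation (smallest adjusted p = 0.892 with an estimated correlation) or by fry (smallest adjusted p = 0.862), and no member gene was called over all genes tested. Adjusted over the list alone, 5 member genes were called over all lists and strains. Leaving out WT replicate 1 leaves WT replicate 2 as the only WT array, and its URA3 of 11.95 opposes that label. Calls kept or lost there may thus rest on an array of another strain. Without WT replicate 1 the count of pairs was 48, of which 24 kept their call and direction, 23 were not called with all arrays and 1 turned its direction; none was called with an estimated correlation (smallest adjusted p = 0.977 with an estimated correlation). Ribosome biogenesis genes were called lower in 6 of 7 strains, with medians down to -0.30 (log2) in MA6, where 86 members were measured. Without WT replicate 1 MA6 alone kept that call, with a median of -0.10, and in MA3 the list was called higher relative to the other genes, with a median of -0.01. Mitochondrial ribosomal protein genes were called higher in 7 strains, and in 5 of them without WT replicate 1. Environmental stress response genes were called higher in 6 strains, of which MA6 alone was left without that array. Cell wall integrity genes were called higher in 5 strains, of which 3 were left. The calls of tricarboxylic acid cycle genes in 6 strains and of pleiotropic drug resistance genes and trehalose and glycogen genes in 5 each all ended without WT replicate 1, and the last list kept 3 without MA8 replicate 2. MA5, in which none of the lists named so far except the mitochondrial ribosomal proteins was called with all arrays, had ribosome biogenesis genes called higher without WT replicate 1 (median 0.16). Stress response (-0.27), cell wall integrity (-0.27), tricarboxylic acid cycle (-0.16), pleiotropic drug resistance (-0.31) and trehalose and glycogen genes (-0.24) were then called lower in MA5. Cytosolic ribosomal protein genes, called higher in 2 strains with all arrays, were called higher in all 7 without that array, with medians from 0.02 to 0.11. Heat shock protein and cytosolic chaperone genes were called higher in 4 strains. In MA7, where all 24 members were higher (median 0.25), that call held without each array in turn, and in MA3, MA6 and MA8 it ended without WT replicate 1. Respiratory chain and ATP synthase genes were called higher in 4 strains and held without each array in turn in MA6 (median 0.16), while the calls in MA1, MA5 and MA7 ended without WT replicate 2. In all, 13 of the 83 pairs held without each array in turn. With all arrays the smallest adjusted p of any of these lists was 0.892 with an estimated correlation.

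Leading members of these lists had values that missed the test. UTP15, of the small-subunit processome that builds ribosomes, was 11.09 ± 0.11 (SD, n = 2) in MA6 and 11.68 ± 0.19 in WT, a log2 change of -0.59 ± 0.12 (SE, limma adjusted p = 0.40). Its change was -0.44 in MA7 and -0.39 in MA8. DIP2, of the same complex, had -0.41 in MA2 and -0.37 in MA3, and UTP30 -0.46 in MA1. ATP20, a subunit of the mitochondrial ATP synthase, differed by 0.46 ± 0.11 in MA6 (limma adjusted p = 0.40). GRX1, a glutaredoxin of the stress list, had 0.51 in MA6 and 0.47 in MA7, and PAI3, an inhibitor of the protease Pep4, had 0.93 in both MA1 and MA8. GSC2, a glucan synthase subunit of the cell wall list, had 1.41 ± 0.65 in MA1, where its arrays were 12.71 and 11.01. HSP78, a mitochondrial chaperone, had 1.02 ± 0.41 in MA7. XBP1, a stress-induced repressor, had 1.14 ± 0.70 in MA2, with WT arrays at 6.51 and 8.80. ACO1 (aconitase) had 0.56 in MA3, PDR16 of the pleiotropic drug resistance list 0.37 in MA2, HSP150 of the cell wall list 0.28 in MA3, and RPL19A, of the large ribosomal subunit, 0.18 in MA8. Of the mitochondrial ribosomal proteins, MRPL27 had 0.40 in MA1, MRPS16 0.28 in MA2 and 0.43 in MA7, MRPL6 0.19 in MA3, MRPL33 0.25 in MA6 and MRPL37 0.27 in MA8. Leaving out 1 array moved many of these values by over 1.5 times. Without WT replicate 1 the change was -0.26 for UTP15 in MA8, -0.21 and -0.17 for DIP2 in MA2 and MA3, -0.26 for UTP30, 0.44 and 0.43 for PAI3 in MA1 and MA8, 0.42 for HSP78, -0.0002 for XBP1, 0.12 for ACO1, 0.14 for PDR16, 0.10 for HSP150, 0.08 for MRPL6, and 0.12 and 0.27 for MRPS16 in MA2 and MA7. Without WT replicate 2 it was farther from 0 for each of these, and reached 1.00 for ACO1, 1.63 for HSP78 and 2.28 for XBP1. Without MA1 replicate 1 it was 0.56 for GSC2 and 0.22 for MRPL27, and without MA6 replicate 1 it was 0.31 for ATP20.

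MA5 had the fewest probe sets at an unadjusted p under 0.05 against WT, 18, and none 2-fold apart. Arrays labelled MA5 and WT with the same replicate number differed by a root mean square of 0.12 (log2) for each number. The 2 arrays of one label differed by 0.44 in MA5 and by 0.42 in WT. Both means thus average unlike arrays that match across the labels, so these low counts do not show a weak effect of the substitution. The called list of MA5 with the smallest p was cytosolic ribosomal proteins, with a median of 0.05 over 128 members. The list of prefoldin and phosducin-like cofactors (the prefoldin list below) had a median of 0.08 over 7. Prefoldin passes substrates to CCT. Without WT replicate 1 these medians were 0.11 and 0.28. GIM4, a prefoldin subunit, was 10.75 ± 0.01 in MA5 and 10.51 ± 0.06 in WT (log2 change 0.24 ± 0.07, limma adjusted p = 1.00). RPL41A, of the large ribosomal subunit, had 0.67 ± 0.32 in MA5, and 0.04 without MA5 replicate 1. ATP15, of the mitochondrial ATP synthase, had 0.17, and HMG1, of ergosterol synthesis, had -0.09, and -0.05 without MA5 replicate 2. The calls of the cytosolic ribosomal protein and prefoldin lists were lost as well (smallest adjusted p = 0.892 with an estimated correlation), and also without WT replicate 2 or without MA5 replicate 1. The lists of CCT subunits, CCT client proteins, septins and the unfolded protein response were called in no strain. Actin cytoskeleton genes were called higher in MA8 with a median of 0.05, and microtubule genes lower in MA7 with a median of -0.11, both with an adjusted p = 0.892 or more with an estimated correlation. Both calls ended without WT replicate 1, that of MA8 also without WT replicate 2 or MA8 replicate 2, and that of MA7 also without MA7 replicate 2.

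Taken array by array, the lists differed between arrays of the same label. The array labelled WT replicate 1 had all 27 stress response genes below their 16-array median (list median -0.67), all 8 pleiotropic drug resistance genes below (-0.67), and all 86 ribosome biogenesis genes above (0.39). The array labelled MA5 replicate 1 had list medians of -0.50, -0.53 and 0.36 for the same lists, whereas WT replicate 2 had 0.04, -0.01 and 0.00. HSP12, a small membrane-protecting stress protein, was 10.82 on WT replicate 1, 10.56 on MA5 replicate 1 and 12.84 on WT replicate 2. The 3' minus 5' difference of the SPT15 control probe sets was 1.37 and 1.21 on WT replicate 1 and MA5 replicate 1 and at least 1.47 on the other 14 arrays. The same difference for ACT1 (0.44 and 0.42) and RIP1 (0.25 and 0.31) did not set both arrays apart. For WBP1 it was 1.55 and 1.36, and also 1.55 on MA8 replicate 1. The 25S ribosomal RNA control was 11.27 on WT replicate 1 and 7.22 on MA5 replicate 1. Pheromone response genes had medians of 0.41 and 0.36 on WT replicate 1 and MA5 replicate 1, with FUS1 (cell fusion) at 8.59 and 8.66 against a 16-array median of 7.30.

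The arrays labelled MA1 replicate 1 and MA6 replicate 1 had all 15 cell wall integrity genes above their 16-array medians (list medians 0.59 and 0.64). Stress response genes had medians of 0.40 and 0.63 there, glucose-repressed genes 0.48 and 0.43, and sporulation genes 0.60 and 0.54. Genes specific to a cells were low, at -0.56 and -0.62, with the pheromone receptor STE2 at 11.95 and 11.90 against a median of 12.51. PIR3, a cell wall protein, was 12.95 on both, against 9.55 and 10.09 on the second arrays of those labels. ADH2, the glucose-repressed alcohol dehydrogenase, was 10.29 and 10.19 against 6.54 and 6.52.

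Hypoxic genes were low on 6 arrays, with medians of -1.08 on WT replicate 1, -0.91 on MA5 replicate 1, -0.90 on MA1 replicate 1, -1.06 on MA6 replicate 1, -1.46 on MA3 replicate 1 and -1.18 on MA7 replicate 2. No other array had a median below -0.09. DAN1 and TIR1, cell wall mannoproteins of anaerobic growth, had 16-array medians of 11.30 and 12.73; on WT replicate 1 they were 6.14 and 9.31 and on WT replicate 2 11.61 and 12.95. Among 10000 random lists matched on level, the hypoxic median lay at percentile 0 on each of the 6 arrays. These arrays were named for their low medians, and genes drawn at random need not vary together. The percentile thus describes the arrays and is no test.

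**Figure D3:**
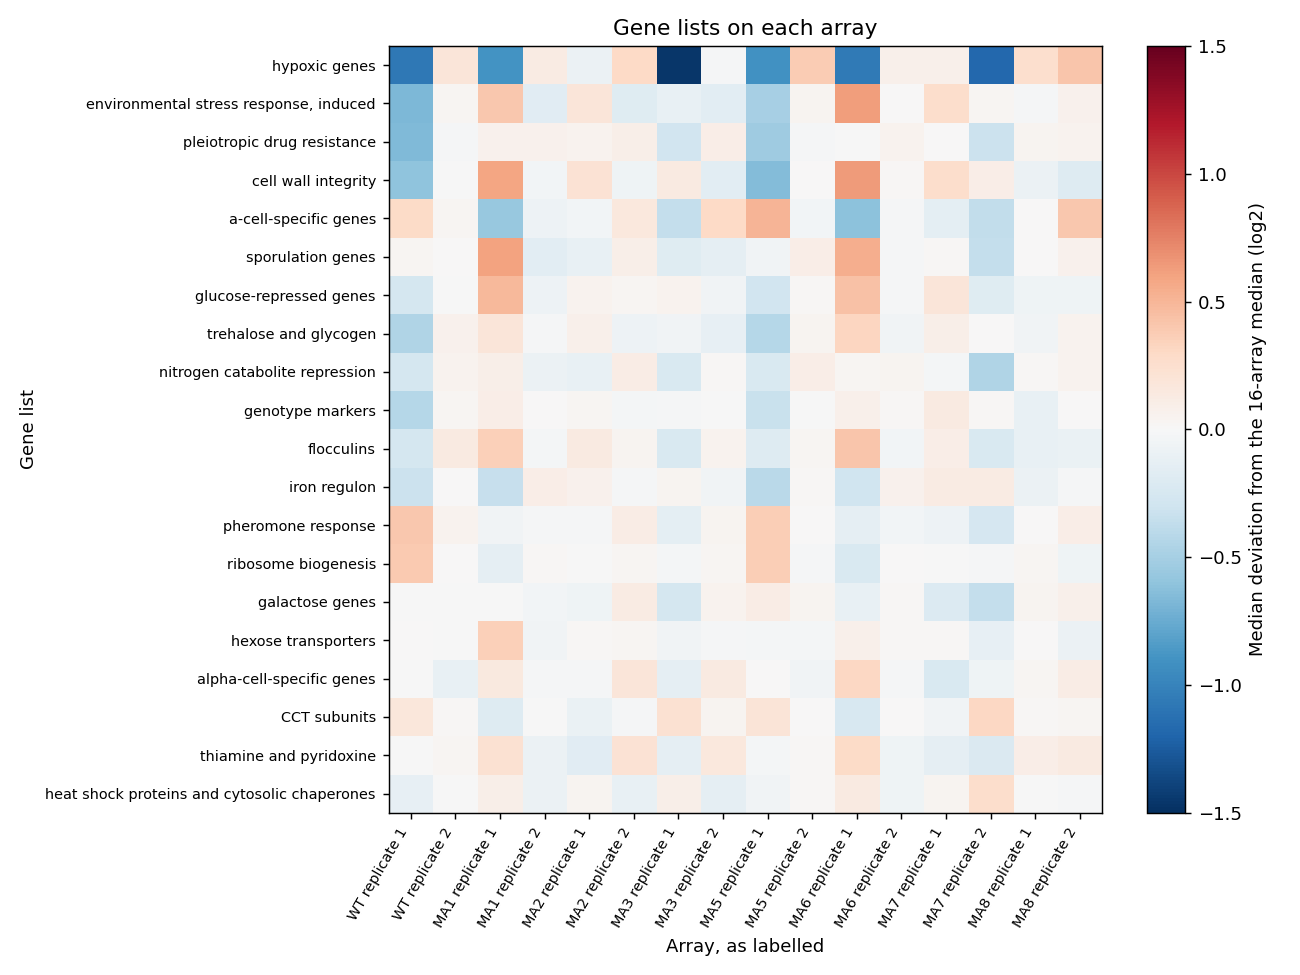
Median deviation of each gene list from the 16-array median (colour, log2) for the 20 lists with the largest absolute median (rows) on the 16 arrays (columns, as labelled), 1 value per array with no error. Hypoxic genes reach -1.46 on MA3 replicate 1, and the 2 arrays of most labels differ in colour.

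Genes of chromosome X stood apart on 2 arrays. Their median deviation, over 316 genes, was 0.72 on the array labelled MA3 replicate 1 and 0.77 on MA7 replicate 2, a level of 1.64 and 1.71 times the 16-array median. On those arrays the other 15 chromosomes had medians between -0.09 and -0.02, and on the other 14 arrays chromosome X lay between -0.03 and 0.02. CCT3, CCT5, CCT7 and CCT8 lie on chromosome X and were high on the same arrays, at 13.03 and 13.21, 13.63 and 13.73, 12.72 and 12.95, and 13.48 and 13.54. The CCT list median there was 0.23 and 0.31, and 0.03 and 0.00 without the genes of chromosome X.

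**Figure D4:**
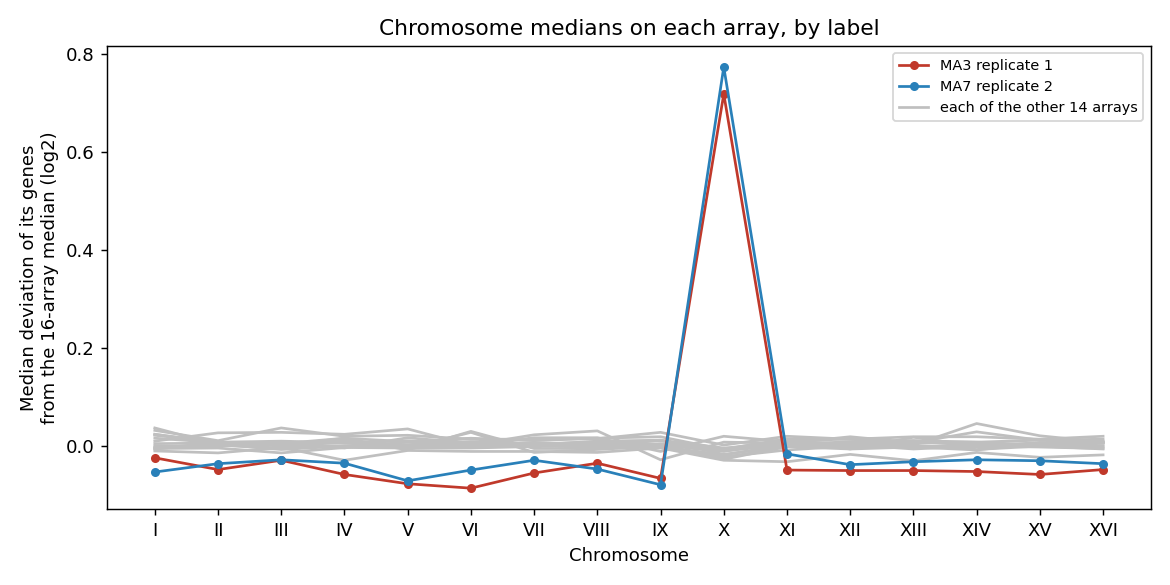
Median deviation of a chromosome's genes from the 16-array median (vertical axis, log2) for the 16 chromosomes (horizontal axis), 1 line per array. On chromosome X the arrays labelled MA3 replicate 1 and MA7 replicate 2 reach 0.72 and 0.77, and no other array exceeds 0.02 there.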

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

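All tests in this part were chosen after the values were seen, except that of URA1 and URA4 against the marker. Signals outside the tested genes came from reporter, control and unnamed probe sets, which no comparison used. Here values not above the S. pombe background level of 5.40 were set to it, so a difference from such a value is a bound. The reporter probe set RPTR-Sc-AJ002682-2_s_at was 7.12 on MA2 replicate 1 and 7.02 on MA7 replicate 1 and not above background on the WT-labelled arrays, which lay at least 1.72 (log2) below the first value. The probe sets J01347-1_s_at, J01347-2_at, J01347-3_at, J01347-4_at and U46493-1_s_at of 2 reporters were not above background on the arrays labelled MA1 replicate 2 and MA6 replicate 2. Against the lower WT-labelled array the bounds were -2.02, -7.10, -5.61, -6.87 and -3.70 in that order. These identifiers are not paired with genes in the tables used here. At least 1 mutant-labelled array was 2-fold or more above both WT-labelled arrays for 2 control and 12 unnamed probe sets, and for no S. pombe probe set. At least 1 was 2-fold or more below both for 16 control probe sets, of which 10 are for ribosomal RNA by name and were lowest on MA5 replicate 1. The unnamed probe set with the largest excess was 3.41 above, at 12.17 on MA6 replicate 1 and 12.04 on MA1 replicate 1.

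URA3 opposed the genotype label on 6 arrays, 3 in each direction, as an exchange of labels or columns needs. With 4 low arrays and 4 labels without the marker, the counts in both directions had to be equal. Their balance is therefore no further evidence of an exchange. A fault of 1 probe set was argued against by the same 4 lowest arrays in all 4 URA3 probe sets. Uracil in the medium, which acts on several pyrimidine genes together, was argued against by URA1, whose median was 0.506 (log2) higher, not lower, on the arrays with low URA3. Over all tested genes, 2 of 16 arrays lay nearest to the other array of their label, which is also consistent with exchanged labels. A batch of labelling or hybridization could not be excluded for that part: the S. pombe probe sets gave 5 arrays the same nearest array, with correlations of at most 0.064. URA3 shows only exchanges between marked and unmarked strains, so more than these 6 arrays may be out of place, and any comparison of strains above may then be one of other strains than it names. Which label belongs to which array was not determined, and no array was reassigned.

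The chromosome X signal may come from an extra copy of the chromosome, a hypothesis. The lowest median of 20 neighbouring genes on chromosome X was 0.477 over both arrays, so no part of it lay near the level of the other arrays. Normalization by expression level was argued against by 1000 random lists of other genes matched on level, whose highest median was -0.008. A few strongly changed genes were argued against by 97.15% of the chromosome's genes lying above their 16-array medians on each array. DNA was not measured, and since the arrays carry different labels no biological explanation by strain was tested.

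The marker prediction, written before the data were examined, was that URA1 and URA4 would set MA6, which lacks the URA3 marker by label, apart from the 6 marked mutants. Their median change in MA6 was -0.289 (log2), inside the range of -0.297 to 0.021 of the others but 0.008 from its end, with a standard error of 0.24. Inside that range was to count against the marker. That bound assumed labels which URA3 itself contradicts, so marker and substitution cannot be told apart here.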

How the results depend on the processing

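Under the alternatives fixed before the data were examined, the 11 counts of called probe sets stayed at 0, the replicate block included (0 calls in each). Replicate numbers paired arrays of some strains but not of all. Over 28 pairs of strains the differences between replicates correlated from -0.663 to 0.929 (median 0.035), above 0.1 in 7. Arrays labelled WT and MA5 with the same number were close (r = 0.94 and 0.57), as were those of MA1 and MA6 (0.93 and 0.57). In contrast, MA3 replicate 1 lay nearest to MA7 replicate 2 (0.85). The added fit without the 6 arrays whose URA3 opposes the label gave 1 call in each of MA1, MA2, MA3, MA5, MA7 and MA8, in all cases URA3, by the construction of that alternative; MA6 had no array left, so counts over 7 mutants were not computed. The 83 list and strain pairs became 0 with an estimated correlation and 0 with fry. In camera the correlation was the setting changed, so the 83 calls rest on its preset value of 0.01. For ribosome biogenesis in MA1 the unadjusted camera p was 2.4e-14 with the preset and 0.23 with the estimated correlation. Why fry called none was not tested. The count of pairs was 68 after another quantile normalization and 77 with the replicate block. Without the 6 arrays it was 84 of 282 pairs in 6 strains, which had 71 of the 83 calls, and 52 pairs were called in both in the same direction. Leaving out each array in turn gave 48 (without WT replicate 1, and 0 there with an estimated correlation) to 99 (without WT replicate 2). None of the 42 log2 changes of named genes was called under any alternative fixed before the data were examined (966 values, so without the added fit that called URA3), and 18 values, all from leaving out an array, changed sign. Over the left-out arrays the change ranged from -0.14 to 0.021 for CCT2 in MA2, -0.062 to 0.59 for CCT3 in MA3, -0.10 to 0.063 for CCT5 in MA5, -0.13 to 0.75 for CCT6 in MA6, -0.21 to 0.51 for CCT7 in MA7, -0.071 to 0.13 for CCT8 in MA8 and -0.0002465 to 2.28 for XBP1 in MA2. For URA3 it ranged from -0.14 to 3.74 in MA1, -2.77 to 1.90 in MA2, -0.11 to 3.77 in MA3, -1.91 to 1.97 in MA5, -0.15 to 3.73 in MA6, 0.088 to 3.97 in MA7, where the sign did not turn, and -2.71 to 1.90 in MA8, set in each case by which array of WT or of the strain was left out. A lone array left in a strain was assumed to vary like the others. Without the 6 arrays this held for WT, and the lists were not tested there with an estimated correlation. Without WT replicate 1 the lone WT array was WT replicate 2, whose URA3 opposes its label. The count of arrays nearest to their own label stayed at 2, and the chromosome X medians stayed between 0.72 and 0.77, in the alternatives run for them, all added after the data were seen. By the S. pombe probe sets these 2 were other arrays, MA6 replicate 2 (r = 0.037) and MA7 replicate 2 (r = 0.026). The MA8 arrays had r = -0.015 there, so that equal count does not show a stable result. Of the tested probe sets, 155 did not exceed the S. pombe background level of 5.40 in any strain, so their differences are the least certain.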

Other observations

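Genes with the widest range over the 16 arrays, chosen after their values were seen, parted arrays of the same label as well. Of 5449 genes, 905 spanned at least 2-fold and 174 at least 4-fold. PHO84, the high-affinity phosphate transporter, had the widest range (6.36 log2), with 6.63 on the array labelled MA3 replicate 1 and 5.80 on MA7 replicate 2 against a 16-array median of 10.33. DAL4, the allantoin permease, was 9.89 on MA1 replicate 1 and 9.99 on MA6 replicate 1, with a median of 6.47. FLO1, a flocculin, was 9.20 and 9.63 on those arrays, with a median of 7.30. YAR068W was 10.99, 10.59 and 10.87 on MA3 replicate 2, MA8 replicate 1 and MA8 replicate 2, with a median of 8.88.

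RPS22B, 1 of a pair of genes for a protein of the small ribosomal subunit, was 9.46 on the array labelled MA3 replicate 1 and 9.62 on MA7 replicate 2, and at least 13.23 on the other 14. RPS22B lies on chromosome XII. Its partner RPS22A lies on chromosome X and was 13.42 and 13.65 on those arrays, within or close to the range of 13.06 to 13.57 of the others. The flanking genes GRX8 and MDM30 were 8.67 and 9.42 on MA3 replicate 1 and 9.01 and 9.45 on MA7 replicate 2, against 8.45 and 9.32 on WT replicate 2.

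Iron regulon genes had medians of -0.32, -0.41, -0.34 and -0.30 on WT replicate 1, MA5 replicate 1, MA1 replicate 1 and MA6 replicate 1, and 0.12 on MA7 replicate 2. Heat shock protein and cytosolic chaperone genes had their highest median on MA7 replicate 2, 0.27, with 22 of 24 members above their 16-array medians.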
